A study of Mus musculus with 23 samples.

How the data were processed

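Messenger RNA was isolated from purified mammary epithelial cell types of female C57BL/6 mice, turned into biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The labels give each array a reproductive stage and a cell type. They do not describe the surface markers or gates used for the purification, and they do not say whether arrays of one group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

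The authors deposited 1 table with a log2 expression value for each of 45101 probe sets on each of the 23 arrays. The log2 scale was read from the deposited values themselves, which ran from 0 to 14.28 with array medians between 4.51 and 5.47. Between 1.24% and 2.34% of the probe sets on an array were listed at 0, so a value at 0 was treated as a floor. No detection calls were used here, so differences from a low value can include background and are no exact folds. A setting added after seeing the data raised every value below the median of its array to that median. The software that summarised the probes, corrected the background and scaled the arrays is not given in the sources used here. The 75th percentiles of the arrays lay between 7.77 and 8.32 and were not identical, so the deposited values had not been forced to one common distribution. The values were used as deposited, and no pseudocount was added. Any pair of arrays differed in at least 98.5% of its probe sets, so no array was present more than once.

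Probe sets were named through the annotation of the array platform. Of the probe sets that are not array controls, 34945 listed 1 gene symbol. A further 932 listed several symbols and 9160 had no gene listed, and none of these was named. Entrez identifiers of 34741 probe sets were found in a mouse gene table, and 0 symbols had to be updated. The named probe sets covered 18193 genes, of which 9010 had 2 or more probe sets. Each gene was represented by the probe set with the highest mean over all arrays. A gene was kept if its value lay above the 40th percentile of its array on at least 2 arrays, which left 15378 genes. Genome coordinates were not used here. For arrays, precision is limited by their number.

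The 23 arrays formed 16 groups of 1 stage and 1 cell type. Because 9 groups had 1 array, a single linear model with 1 mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3, with a spread moderated by eBayes along an intensity trend. It had 7 residual degrees of freedom and 4.74 prior degrees of freedom. The 9 groups with 1 array were assumed to vary like the 7 groups with 2. Differences between cell types were averaged with equal weight over the 5 stages that have both types, and differences between stages over the 3 cell types. Differences between stages were also tested within each cell type, and the stage effects in stem cells and in mature luminal cells were compared by an interaction. All tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. Values after ± are standard errors from the same model unless they are called SD.

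The comparisons, the model, 28 gene lists with 472 members and the alternative settings were chosen before the data were examined. The lists hold epithelial marker, pathway and process genes together with markers of other cell types that a preparation could hold, and 426 members were among the genes kept. Lists were tested with camera, a test of whether the genes of a list shift relative to all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Each list was tested again with a correlation estimated from the data. The named genes follow a rule that was fixed together with the lists. It takes up to 10 genes per direction, or 5 within 1 cell type, with the largest change among those that passed and moved alike in every stage or cell type compared. It adds up to 4 members of each list with the smallest p in that comparison and a set of 14 genes that were always looked at, among them keratins, hormone receptors, milk proteins and DNA methyltransferases. Of 101 pairs of a named gene and a comparison with more than 1 probe set above the filter, all probe sets moved in the same direction in 97. Probe sets that moved alike could still differ in size, and the other values are given for some genes only.

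Some array titles carry a replicate number. Whether these numbers pair the arrays was checked. Deviations from the group means of the 7 groups of 2 were correlated between groups over the genes, and all 21 pairs of groups had a correlation above 0.1, from 0.303 to 0.682 with a median of 0.470. Among the 14 numbered arrays in groups of 2, each correlated best with an array of the same number. Correlations with arrays outside these groups were left out of that check. All 8 unnumbered arrays lay closer to the arrays titled replicate 2. The number was therefore taken as a batch of arrays, although the labels do not say what it marks. A planned fit used it as a block in the numbered groups of 2. A fit on all arrays, added after seeing the data, had a term that set the 8 arrays titled replicate 1 against the other 15, with 6 residual and 6.63 prior degrees of freedom. Fits within each side of that split were added at the same time, in a model of stage plus cell type instead of 1 mean per group. The lists were tested there with camera in the same model. Of these list calls, 41 within replicate 1 and 74 within the other arrays, 0 passed with an estimated correlation.

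The code was tested on simulated data with the spread of the real arrays, in which a known set of genes was changed among 15378. Each gene also had its fitted replicate difference, the same in every group, and noise independent of the other genes. The real replicate deviations correlated between groups at only 0.303 to 0.682. The shares with the replicate term and the false calls are therefore those of a simpler setting. In the comparison of day-10 pregnancy with 9-week virgins over 3 cell types, 49% of genes changed 4-fold and 89% of genes changed 16-fold were recovered, with 0 false calls. With the replicate term these shares were 86% and 99%, with 10 false calls. In luminal progenitors against stem cells, 69% and 98% were recovered without the term. Within stem cells at day 10 the shares were 12% and 56%, and for the single retired breeder stem array they were 2% and 37%. Alternatives covered the filter, the choice of probe set, quantile normalization, the moderation of the spread, the model, the arrays entering the fit and the removal of each array in turn. Where the only array of a group was removed, its stage or cell type left the average. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.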

Results

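Gene expression was measured on 23 Affymetrix arrays of epithelial cells purified from the mammary glands of female C57BL/6 mice, an inbred strain. The labels distinguish 3 cell types, stem cells, luminal progenitors and mature luminal cells. The luminal cells line the ducts and make milk, and the stem cell preparations carried the markers of the outer, basal layer. The reproductive stages were virgin mice of 3 and 9 weeks, days 10, 16 and 19 of pregnancy, and retired breeders, which have been through earlier pregnancies. Of the 16 groups of stage and cell type, 7 had 2 arrays each, namely the 3 cell types of 9-week virgins, the stem cells and luminal progenitors of 3-week virgins, and the stem and mature luminal cells of day 10. The other 9 groups had 1 array each, and day 19 was measured in mature luminal cells only. Retired breeders differ from virgins in parity and in age, and the design does not separate the 2.

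The deposited log2 values had array medians between 4.51 and 5.47. Hybridisation signal from the 3′ end of Gapdh exceeded that from the 5′ end by 0.87 to 2.72 log2 units on 21 arrays, by 3.77 on the retired breeder stem array and by 5.16 on the 3-week mature luminal array. A larger excess is usually read as more degraded RNA. The 2 arrays of a group correlated at 0.876 to 0.941 over all probe sets. The estimate of the spread therefore came from 7 of the 16 groups. The first principal component held 24.6% of the variance. Its scores ran higher on arrays titled replicate 1, with an overlap, as the plot of principal components shows. Among the 14 numbered arrays in groups of 2, each correlated best with an array of the same number. For that reason counts are also given from a fit with a term for the replicate number, and for averages over stages or cell types within each side of that split where arrays allowed.

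**Figure D1:**
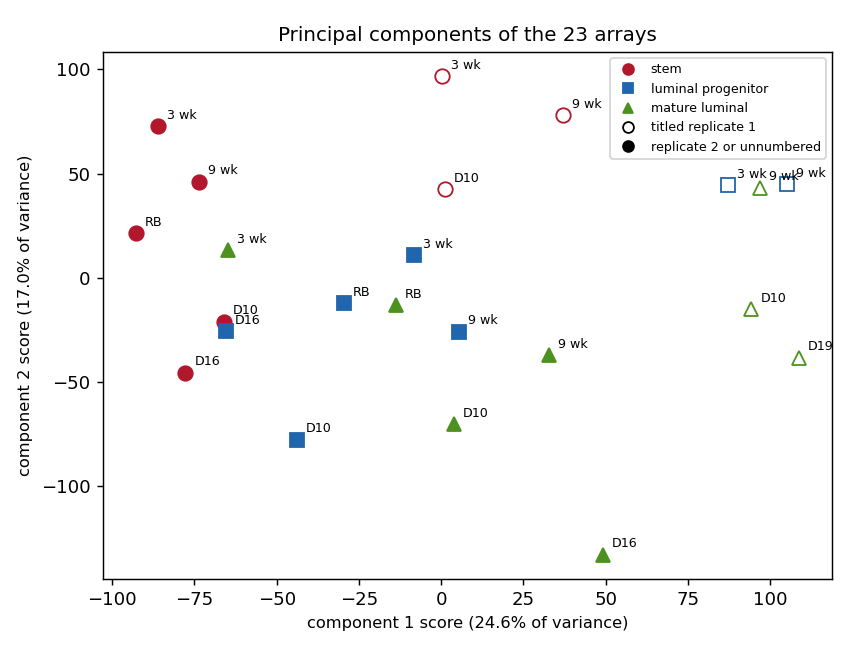
Each point is 1 of the 23 arrays, placed by its scores on the first 2 principal components of 15378 genes, with colour and shape for the cell type, open symbols for arrays titled replicate 1 and a letter code for the stage (3 wk and 9 wk, virgin; D10, D16 and D19, days of pregnancy; RB, retired breeder). Scores on component 1 ran from 0.139 to 108.8 in replicate 1 and from -92.7 to 49.2 on the other arrays.

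The first comparison asked which genes separate luminal progenitors from stem cells at any stage. Luminal progenitors had less of the keratins Krt5 (-3.19 ± 0.69 log2) and Krt14 (-1.90 ± 0.37), of the smooth muscle myosin Myh11 (-3.64 ± 0.67) and of the hemidesmosome collagen Col17a1 (-3.94 ± 0.71). All 4 were lower at each of the 5 stages, with limma adjusted p of 0.0259, 0.017, 0.0136 and 0.0129. They had more of the epithelial transcription factor Ehf (1.62 ± 0.36, adjusted p = 0.0296), the retinaldehyde dehydrogenase Aldh1a3 (1.85 ± 0.40, adjusted p = 0.0246), the hormone-sensing regulator Foxa1 (1.39 ± 0.27, adjusted p = 0.016) and the trafficking protein Mal2 (2.64 ± 0.35, adjusted p = 0.00674). They also had more of the protease inhibitor Cst7 (2.96 ± 0.60, adjusted p = 0.0193), but its difference was 0.18 and did not pass with values below the median of their array raised to it. The calgranulin S100a8 was 3.12 ± 0.78 higher (adjusted p = 0.0449), and within the arrays titled replicate 1 its difference was -0.18. Kit was 1.10 ± 0.36 higher with an adjusted p of 0.123, which became 0.045 with the replicate term, and Elf5 was 1.30 ± 0.52 higher with an adjusted p of 0.203. Esr1 was 1.13 ± 0.29 higher with an adjusted p of 0.0502, which became 0.0118 with the replicate term. Krt18 was 0.62 ± 0.27 higher with an adjusted p of 0.231, which became 0.00556.

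Of 15378 genes, 120 were higher and 553 lower in luminal progenitors than in stem cells. Basal and myoepithelial markers were lower for 12 of 19, among them Tagln (-2.62), Snai2 (-2.88) and Jag2 (-2.75), and for 17 when adjusted over the list alone (camera adjusted p = 1.05e-14). Extracellular matrix and basement membrane genes were lower for 10 of 26, with 1 higher and 12 lower when adjusted over the list alone (camera adjusted p = 3.73e-06), for example Lamb1 (-2.29), Lama3 (-2.51) and Col4a1 (-2.11), which code for parts of the basement membrane. Another probe set of Lama3 gave -0.08. The Wnt pathway had 4 of 22 members lower, 8 when adjusted over the list alone (camera adjusted p = 0.000761), including Wnt10a (-3.68), Dkk3 (-2.61) and the feedback gene Axin2 (-1.90), whose other probe set gave -0.12. The TGF-beta pathway had 5 of 20 lower, 8 when adjusted over the list alone (camera adjusted p = 0.00826), led by Smad6 (-2.73). The Notch pathway had 6 of 16 lower, also 6 when adjusted over the list alone, with the ligand Dll1 at -2.49 and the receptor Notch4 at -2.22. Its camera adjusted p of 0.0302 became 0.1 with the replicate term. Luminal keratins and junction genes had 1 of 14 higher, 2 when adjusted over the list alone (camera adjusted p = 3.73e-06). Milk protein and secretion genes had 2 of 15 higher, 2 when adjusted over the list alone (camera adjusted p = 0.000115), namely the casein Csn3 (1.05) and the folate receptor Folr1 (2.40). For each of these lists the camera call was lost at adjusted p = 0.249 with an estimated correlation. Within the arrays titled replicate 1 the camera adjusted p was 0.399 for the Wnt list, 0.186 for TGF-beta, 0.0885 for Notch and 0.07 for milk protein genes, and the Notch list did not pass within the other arrays either (0.181). Endothelial markers moved with the stem cell preparations, since 4 of 12 were lower in luminal progenitors, 8 when adjusted over the list alone (camera adjusted p = 4.03e-07, and adjusted p = 0.249 with an estimated correlation), for example Esam (-1.87) and Plvap (-1.64).

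With the replicate term 2220 genes differed between luminal progenitors and stem cells, with the planned block 1744, within the arrays titled replicate 1 366, and within the other arrays 917. The count fell to 311 without 3-week stem replicate 2, 355 without the day-10 luminal progenitor array, 419 without 3-week luminal progenitor replicate 1 and 428 without replicate 2 of that group. Quantile normalization moved the median difference of all genes from -0.04 to 0.08 and the share of calls that were higher from 17.8% to 30.8%.

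Mature luminal cells were compared with stem cells in the same way. The smooth muscle actin Actg2 (-5.64 ± 0.53 log2, adjusted p = 0.000293), the cytokine Il17b (-5.53 ± 0.67, adjusted p = 0.000686), the Wnt inhibitor Wif1 (-5.48 ± 0.79, adjusted p = 0.00141) and the secreted glycoprotein Reln (-5.39 ± 0.52, adjusted p = 0.000319) were the furthest below their level in stem cells, at all 5 stages. The growth factors Nrg1 (-4.19 ± 0.40) and Ereg (-4.55 ± 0.64), both ligands of the ERBB receptors, and the integrin Itgb3 (-3.94 ± 0.40, with -1.24 from another probe set) were lower as well. With low values raised to the array median Wif1 was at -3.71, less far down than Ereg at -4.24, so its rank rests on low values. Higher in mature luminal cells were the arginase Arg1 (3.41 ± 0.49, adjusted p = 0.00135), the amino acid transporter Slc6a14 (3.06 ± 0.56), the ribonuclease Rnase1 (3.03 ± 0.58) and the chloride channel Cftr (2.93 ± 0.42). The call of Rnase1 was lost, at 0.96, with low values raised to the array median. The oestrogen receptor Esr1 was 1.06 ± 0.29 higher (adjusted p = 0.0438) and Foxa1 1.42 ± 0.27 higher (adjusted p = 0.00634). Krt5 was -2.90 ± 0.69 (adjusted p = 0.0235) and Krt14 -1.43 ± 0.37 (adjusted p = 0.0347), and Krt18 was 0.69 ± 0.27 with an adjusted p of 0.149, which became 0.00206 with the replicate term.

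In all, 240 genes were higher and 1043 lower in mature luminal cells. Extracellular matrix and basement membrane genes were lower for 20 of 26, 23 when adjusted over the list alone (camera adjusted p = 4.47e-21), including Lamb1 (-3.25), Nid1 (-3.15) and Col4a1 (-3.19). That call was lost at adjusted p = 0.0717 with an estimated correlation. Basal and myoepithelial markers were lower for 15 of 19, 17 when adjusted over the list alone (camera adjusted p = 8.82e-16), with Tagln at -3.50, Snai2 at -3.78, Acta2 at -2.94 and Vim at -1.65. The TGF-beta pathway had 8 of 20 members lower, 9 when adjusted over the list alone (camera adjusted p = 0.000482). The Notch pathway had 7 of 16, also 7 when adjusted over the list alone (camera adjusted p = 0.00153), with Dll1 at -3.15. These 3 lists, and the endothelial markers, were lost at adjusted p = 0.0953 with an estimated correlation. Endothelial markers were lower for 8 of 12, 11 when adjusted over the list alone (camera adjusted p = 4.21e-09). Fibroblast and stromal markers were lower for 4 of 10, 8 when adjusted over the list alone (camera adjusted p = 3.56e-05, and adjusted p = 0.263 with an estimated correlation), including Col3a1 (-3.49) and Dcn (-2.66). Luminal keratins and junction genes were higher for 2 of 14, Ehf (1.95) and Cldn4 (2.04), and for 11 when adjusted over the list alone (camera adjusted p = 3.81e-07, and adjusted p = 0.168 with an estimated correlation). Fatty acid and triglyceride synthesis had Scd1 (1.52) and Gpam (1.16, and 0.23 from another probe set) among 2 of 20 higher, 2 when adjusted over the list alone, at a camera adjusted p of 0.0286 that became 0.109 with the replicate term and was an adjusted p = 0.289 with an estimated correlation. Within replicate 1 and within the other arrays its camera adjusted p was 0.424 and 0.129, and within replicate 1 the TGF-beta and Notch lists had 0.36 and 0.137.

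Between mature luminal and stem cells 3023 genes differed under the replicate term, within the arrays titled replicate 1 322 and within the other arrays 1755. Without the day-16 stem array the count was 683 and without the day-16 mature luminal array it was 704.

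Mature luminal cells and luminal progenitors had the fewest differing genes of the 3 pairs of cell types, with 1 gene higher and 18 lower in mature luminal cells. Among the lower genes were the proteoglycan Lum (-4.48 ± 0.72 log2, adjusted p = 0.0438), the collagen Col1a1 (-3.97 ± 0.57, adjusted p = 0.0252), the stromal antigen Cd248 (-3.94 ± 0.62, adjusted p = 0.0415), Igfbp6 (-4.42 ± 0.63, adjusted p = 0.0246), Lyve1 (-3.31 ± 0.45, adjusted p = 0.0228), Bmper (-3.24 ± 0.44, adjusted p = 0.0228), Fn1 (-2.81 ± 0.34, adjusted p = 0.0224) and Nid1 (-2.54 ± 0.33, adjusted p = 0.0226). The progenitor marker Itgb3 was also lower (-2.79 ± 0.41, adjusted p = 0.0261, with -0.62 from another probe set), and the 1 gene that was higher, named after its value was seen, was Atp6v0d2 (2.74, adjusted p = 0.0373), a subunit of the vacuolar proton pump. With low values raised to the array median Lyve1 (-2.00) and Itgb3 (-1.97) lost the call. Igfbp6 (-2.09), Cd248 (-2.06), Bmper (-1.79) and Atp6v0d2 (1.65, below the median on 19 arrays) then kept it. Aldh1a3 was -1.08 ± 0.41 with an adjusted p of 0.8, which became 0.0478 with the replicate term.

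Fibroblast and stromal markers were lower in mature luminal cells for 2 of 10, and for 9 when adjusted over the list alone (camera adjusted p = 6.79e-23). Their mean reached 10.31 and 10.71 on the day-10 and day-16 luminal progenitor arrays against 4.10 on the day-16 mature luminal array. Extracellular matrix and basement membrane genes were lower for 3 of 26, 13 when adjusted over the list alone (camera adjusted p = 6.79e-23). Both of these calls held at adjusted p = 0.0393 with an estimated correlation. Under the replicate term both passed at the preset correlation (camera adjusted p = 3.94e-20) and were lost at adjusted p = 0.118 with an estimated correlation. Oxidative phosphorylation shifted up (camera adjusted p = 8.35e-07, and adjusted p = 0.192 with an estimated correlation), with 0 of 19 members past the gene test in limma and 0 when adjusted over the list alone. With the replicate term 153 genes differed, with the planned block, at 9 weeks alone, 2, within replicate 1 1 and within the other arrays 22. Quantile normalization gave 37 genes, and the fit on only the groups compared 1. The count fell to 1 without both luminal progenitor arrays of days 10 and 16, to 0 without the day-10 one (1155 at an unadjusted p under 0.05) and to 2 without the day-16 one. It was 2 without the day-16 mature luminal array, 10 without 9-week mature luminal replicate 2 and 63 without the 3-week mature luminal array.

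Next, 3-week virgins, before puberty, were compared with 9-week virgins, as an average over the 3 cell types. At 3 weeks 25 genes were higher and 2 lower. Those that rose include the scavenger receptor Stab2 (4.54 ± 0.47 log2, adjusted p = 0.0101), the platelet chemokine Pf4 (4.08 ± 0.60), the coagulation inhibitor Tfpi (3.39 ± 0.51), Lyve1 (3.11 ± 0.50), a marker of lymphatic vessels and some macrophages, and elastin, Eln (3.06 ± 0.51), the last 4 each at an adjusted p of 0.0485. The haemoglobin chain Hbb-b2 was 6.74 ± 1.14 higher (adjusted p = 0.0485), with 13.09 on the 3-week mature luminal array. The tryptophan-degrading enzyme Ido1 (-3.21 ± 0.55, adjusted p = 0.0496) and the mechanosensitive channel Piezo2 (-1.33 ± 0.22, adjusted p = 0.0485) were lower. The proliferation gene Mki67 was 1.59 ± 0.52 higher with an adjusted p of 0.262, and Ccna2 1.66 ± 0.38 higher with an adjusted p of 0.104, which became 0.0204 with the replicate term.

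Endothelial markers rose at 3 weeks for 1 of 12, Plvap (1.95), and for 8 when adjusted over the list alone (camera adjusted p = 2.17e-08, and adjusted p = 0.506 with an estimated correlation). Extracellular matrix and basement membrane genes rose for 1 of 26, Nid1 (2.20), and for 11 when adjusted over the list alone (camera adjusted p = 6.42e-06). Of the cell cycle genes 0 of 29 passed in limma and 7 were higher when adjusted over the list alone (camera adjusted p = 3.51e-07). Of the fibroblast and stromal markers 0 of 10 passed and 4 were higher when adjusted over the list alone (camera adjusted p = 0.000112). Cytosolic ribosomal protein genes shifted down with 0 of 19 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 3.65e-07). The last 4 lists were lost at adjusted p = 0.561 with an estimated correlation. The ribosomal mean was 12.11 on the 3-week mature luminal array, the one with the Gapdh excess of 5.16, against 12.81 and 12.59 on the 9-week ones. Without that array the median change of the list was -0.10 (camera adjusted p = 0.0206), and within the arrays titled replicate 1 it was -0.04 (camera adjusted p = 0.29). Leukocyte markers shifted up (camera adjusted p = 0.0257, and adjusted p = 0.64 with an estimated correlation), with 0 of 16 past the gene test and 0 when adjusted over the list alone, and their mean was 8.60 on the 3-week mature luminal array. Without that array the camera adjusted p was 0.912, and within replicate 1 it was 0.788. Quantile normalization moved the median change of all genes from 0.11 to -0.06.

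The replicate term gave 408 genes in this comparison, the planned block, over stem cells and luminal progenitors only, 17, the arrays titled replicate 1 gave 0 (640 at an unadjusted p under 0.05 in limma) and the other arrays 9. With only the groups compared it was 1. Leaving out any 1 of its 11 arrays brought the count to between 0 and 4, for example 0 without the 3-week mature luminal array (681 at an unadjusted p under 0.05) and 4 without 9-week stem replicate 1. It was also 1 without the filter on low values, under quantile normalization or with robust moderation, and 301 with values below the array median raised to it.

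Day-10 pregnancy was compared with 9-week virgins over the 3 cell types. The genes that fell furthest were the mucin-like Dmbt1 (-9.16 ± 0.72 log2, adjusted p = 6.71e-05), Ido1 (-8.42 ± 0.55, adjusted p = 2.95e-05), the fibrinogen chain Fgb (-7.37 ± 0.44, adjusted p = 2.58e-05), the protease Ctse (-6.34 ± 0.56) and the neurexin Nrxn3 (-6.21 ± 0.48). Another probe set of Ctse gave 0.35, and another of Nrxn3 gave 0.86. With low values raised to the array median Nrxn3 (-3.65) fell less than Prom1 (-4.03) or Pgr (-4.00), so its rank rests on low values. The milk proteins Csn1s2a (6.57 ± 1.21, adjusted p = 0.0179, with 1.26 to 7.26 over its 4 probe sets), Csn1s1 (6.43 ± 0.75, adjusted p = 0.00138) and Wap (4.89 ± 0.52, adjusted p = 0.000849) rose, as did the lipoxygenase Alox12e (5.28 ± 0.40, adjusted p = 6.71e-05), Wfdc12 (5.14 ± 0.47), the thioesterase Olah (4.90 ± 0.83), which releases medium-chain fatty acids, and the Wnt potentiator Rspo1 (4.26 ± 0.48). Csn2 was 6.51 ± 1.61 higher with an adjusted p of 0.0631, which became 0.00407 with the replicate term. Its 9-week arrays had an SD of 4.32 to 5.32 within a cell type. The Wap and Fabp3 averages lean on the 1 luminal progenitor array (9.07 and 8.49).

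Hormone-sensing mature luminal markers fell at day 10 for 7 of 11, and for 9, with 1 higher, when adjusted over the list alone (camera adjusted p = 8.21e-12). Among them were the progesterone receptor Pgr (-4.03 ± 0.58, adjusted p = 0.00499), Esr1 (-2.14 ± 0.33, adjusted p = 0.00699), Foxa1 (-2.21 ± 0.30), Prom1 (-4.03 ± 0.52), Wnt5a (-2.66 ± 0.38, with -3.98 to -0.88 over 4 probe sets) and Cd200 (-2.33 ± 0.26). The call held at adjusted p = 0.0282 with an estimated correlation, and was lost at adjusted p = 0.138 with an estimated correlation and the replicate term together. Milk protein and secretion genes rose for 5 of 15, 11 when adjusted over the list alone (camera adjusted p = 3.09e-10, and adjusted p = 0.129 with an estimated correlation), with the lipase Cel at 2.53. Fatty acid and triglyceride synthesis rose for 2 of 20, 6 when adjusted over the list alone (camera adjusted p = 4.27e-05, and adjusted p = 0.129 with an estimated correlation), with the fatty acid binding protein Fabp3 at 4.63 (1.255 from another probe set) and the acetyl-CoA carboxylase Acaca at 2.04. Within replicate 1 the median change of this list was -0.08 (camera adjusted p = 0.636). Cell cycle genes rose for 4 of 29, 18 when adjusted over the list alone (camera adjusted p = 6.06e-11, and adjusted p = 0.315 with an estimated correlation), with Ccna2 at 1.95 and Mcm7 at 1.39. Mki67 was 2.10 ± 0.52 with an adjusted p of 0.0649, which became 0.00988 with the replicate term. Luminal progenitor markers rose for 2 of 12, 8 when adjusted over the list alone (camera adjusted p = 0.00162, and adjusted p = 0.414 with an estimated correlation), namely the alveolar transcription factor Elf5 (2.99 ± 0.59, adjusted p = 0.0243) and Sox10 (2.59 ± 0.46). Interferon response genes fell for 2 of 16, Usp18 (-3.75) and Stat2 (-2.06), and for 4 when adjusted over the list alone (camera adjusted p = 6.41e-06, and adjusted p = 0.46 with an estimated correlation). The median change of that list was -2.20 within replicate 1 and -0.49 within the other arrays. The replicate 1 arrays of 9-week virgins stood at 10.22, 9.72 and 8.48 in stem, luminal progenitor and mature luminal cells, against 8.48, 7.54 and 7.98 in replicate 2. Growth factors and hormone receptors had 1 of 21 higher, Igf2 (3.36, and 0.925 from another probe set), and 3 lower, among them Fgfr2 (-2.82), with 1 higher and 5 lower when adjusted over the list alone. Their camera adjusted p of 0.0282 became 0.0648 with the replicate term and was an adjusted p = 0.315 with an estimated correlation. It was 0.636 within replicate 1 and 0.138 within the other arrays. The kinase Jak2, which acts below the prolactin receptor, was -1.16 ± 0.20 (adjusted p = 0.0117). Fibroblast markers averaged 10.31 on the day-10 luminal progenitor array against 7.10 and 7.22 on the 9-week ones. Their median change was -1.86 within replicate 1 (camera adjusted p = 2.97e-05, and adjusted p = 0.7 with an estimated correlation) and 2.57 within the other arrays (0.00033, and adjusted p = 0.661 with an estimated correlation), while over all arrays the list did not pass (0.101). Leukocyte markers had a median of 1.18 over all arrays (camera adjusted p = 0.0397, and adjusted p = 0.616 with an estimated correlation), -0.82 within replicate 1 and 1.54 within the other arrays. Basal markers had 0.67 (camera adjusted p = 0.00993, and adjusted p = 0.616 with an estimated correlation), 0.16 and 1.23 in the same order. Endothelial markers had -0.71 (camera adjusted p = 0.0174, and adjusted p = 0.546 with an estimated correlation), -1.96 and -0.05. Of the leukocyte, basal and endothelial markers 0 passed the gene test in limma, and 0, 2 and 0 were past when adjusted over the list alone.

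In total 142 genes were higher and 188 lower at day 10. The replicate term gave 1282, the planned block, over stem and mature luminal cells only, 798, the arrays titled replicate 1 306 and the other arrays 80. With only the groups compared it was 176. The count was 152 without 9-week luminal progenitor replicate 1, 154 without day-10 mature luminal replicate 2, 159 without the day-10 luminal progenitor array, 171 without day-10 stem replicate 1 and 212 without 9-week mature luminal replicate 1. Without both luminal progenitor arrays of days 10 and 16 it was 157.

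At day 16 of pregnancy 223 genes were higher and 282 lower than in 9-week virgins. The amino acid oxidase Lao1 rose by 8.26 ± 1.36 log2 units (adjusted p = 0.00884), Csn1s2a by 7.37 ± 1.37 (1.35 to 8.36 over its probe sets), Csn1s1 by 7.05 ± 0.85, Wap by 7.02 ± 0.59 (adjusted p = 0.000138), the lipogenic regulator Thrsp by 6.87 ± 1.15, Fabp3 by 6.77 ± 0.65, Olah by 6.74 ± 0.94 and the lipolysis inhibitor G0s2 by 5.75 ± 0.82. Dmbt1 (-9.35 ± 0.81), Ido1 (-8.93 ± 0.62), Fgb (-7.64 ± 0.50) and the keratins Krt6a (-7.08 ± 0.68, adjusted p = 0.00026) and Krt4 (-5.87 ± 1.07) fell. Csn2 was 6.91 ± 1.82 higher with an adjusted p of 0.0628, which became 0.0248 with the replicate term. Rspo1 (5.05 ± 0.55) and Pigr (4.46 ± 0.81), the receptor that carries immunoglobulin A into milk, rose, and the cell cycle inhibitor Cdkn1a (-1.36 ± 0.29, adjusted p = 0.0302) and Jak2 (-1.48 ± 0.22) fell.

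Milk protein and secretion genes rose at day 16 for 8 of 15, 13 when adjusted over the list alone (camera adjusted p = 1.29e-11), with Cel at 3.33. Fatty acid and triglyceride synthesis rose for 6 of 20, 8 when adjusted over the list alone (camera adjusted p = 1.55e-06), with the lipoprotein lipase Lpl at 4.71 and Acaca at 2.46. Both lists were lost at adjusted p = 0.068 with an estimated correlation. Hormone-sensing mature luminal markers fell for 8 of 11, and for 9, with 1 higher, when adjusted over the list alone (camera adjusted p = 4.39e-11), with Pgr at -3.33 ± 0.66 (adjusted p = 0.0222), Esr1 at -2.61 ± 0.38 (adjusted p = 0.00397), Foxa1 at -3.03, Prom1 at -5.30 and Cd200 at -2.90. That call held at adjusted p = 0.0366 with an estimated correlation, and was lost at adjusted p = 0.0873 with an estimated correlation and the replicate term together. Cell cycle genes rose for 4 of 29, 19 when adjusted over the list alone (camera adjusted p = 7e-09, and adjusted p = 0.383 with an estimated correlation), with Cdc20 at 2.23 and Bub1b at 2.46. Mki67 was 2.06 ± 0.59 with an adjusted p of 0.082, which became 0.0197 with the replicate term. Luminal progenitor markers had 2 of 12 higher, Elf5 (3.78) and Sox10 (3.02), and 1 lower, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.523 with an estimated correlation). Interferon response genes fell for 1 of 16, Usp18 (-3.87), and for 2 when adjusted over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.591 with an estimated correlation). The interferon mean in stem, luminal progenitor and mature luminal cells was 7.55, 7.89 and 7.32 at day 16. The 9-week values are given above. Within the arrays other than replicate 1 the median change of this list was -0.51 and did not pass (camera adjusted p = 0.135). The luminal progenitor list (0.108) and the growth factor list (0.135) did not pass there either. Growth factors and hormone receptors fell for 4 of 21, with Fgfr2 at -3.15, and with 2 higher and 5 lower when adjusted over the list alone, at a camera adjusted p of 0.0251 that became 0.0889 with the replicate term and was an adjusted p = 0.341 with an estimated correlation. Fibroblast markers averaged 10.71 on the day-16 luminal progenitor array. Basal markers shifted up with 0 of 19 past the gene test in limma and 5 higher when adjusted over the list alone (camera adjusted p = 0.00663, and adjusted p = 0.591 with an estimated correlation). Their median change was 0.70, and 1.22 within the arrays other than replicate 1 (camera adjusted p = 0.00116, and adjusted p = 0.754 with an estimated correlation). Their mean was 10.55 on the day-16 luminal progenitor array against 8.54 and 7.48 on the 9-week ones.

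With the replicate term 1118 genes differed at day 16, and within the arrays other than replicate 1 199 did; the arrays titled replicate 1 hold no day-16 sample. With only the groups compared the count was 135. Without the day-16 mature luminal or stem array the average ran over the other cell types only. The count was 28 without the day-16 mature luminal array, 214 without the day-16 stem array, 230 without 9-week luminal progenitor replicate 1, 285 without 9-week mature luminal replicate 1 and 331 without the intensity trend.

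**Figure D2:**
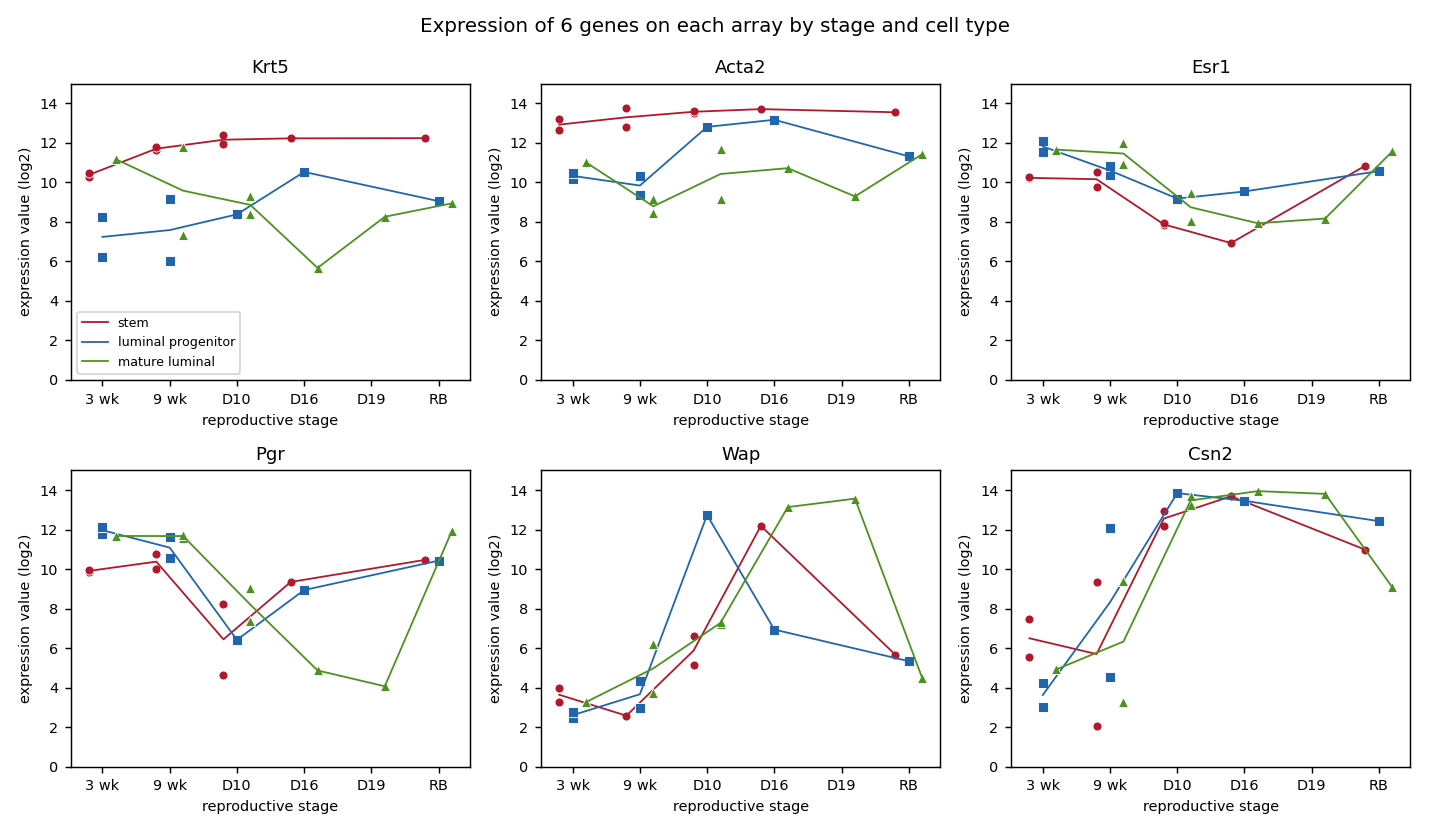
Points are single arrays and lines join the means of a cell type across stages (3 wk and 9 wk, virgin; D10, D16 and D19, days of pregnancy; RB, retired breeder), with the log2 expression value on the vertical axis for Krt5, Acta2, Esr1, Pgr, Wap and Csn2. Wap stood at 12.74 in luminal progenitors at day 10 and 6.94 at day 16, against 7.28 and 13.14 in mature luminal cells.

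Between days 10 and 16, averaged over the cell types, 0 genes passed in limma, with 212 at an unadjusted p under 0.05 and 394 with the replicate term, where 0 passed as well. Within the arrays other than replicate 1 it was also 0 (67 at an unadjusted p under 0.05). Wap was 2.12 ± 0.63 log2 units higher at day 16 (adjusted p = 1) and Thrsp 3.04 ± 1.21 higher (adjusted p = 1). Milk protein and secretion genes shifted up from day 10 to day 16 with 0 of 15 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 2.49e-05, and adjusted p = 0.362 with an estimated correlation). The hormone-sensing markers shifted down with 0 of 11 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.362 with an estimated correlation). Leukocyte and fibroblast markers had medians of -0.21 (camera adjusted p = 0.497) and -0.26 (camera adjusted p = 0.695) over all arrays. Within the arrays other than replicate 1 leukocyte markers had -1.24 (camera adjusted p = 1.07e-08) and fibroblast markers shifted down too (camera adjusted p = 2.06e-05), each at an adjusted p = 0.621 with an estimated correlation, and the milk protein list had 0.53 (camera adjusted p = 6.19e-05). Wap went from 5.17 on the replicate 2 array of day 10 to 12.19 at day 16 in stem cells and from 7.32 to 13.14 in mature luminal cells. In luminal progenitors it went from 12.74 to 6.94. Thrsp went from 6.37 to 11.11, from 8.64 to 12.75 and from 11.95 to 7.84 in the same order of cell types. Without either or both luminal progenitor arrays the average ran over stem and mature luminal cells alone, where 15 genes differed.

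Retired breeders were compared with 9-week virgins to ask what remains after earlier pregnancies and with age. Alox12e was the 1 gene that passed, 4.17 ± 0.45 log2 units higher in retired breeders (adjusted p = 0.0152, and 0.00721 with the replicate term). It stood at 7.80, 7.11 and 7.91 in stem, luminal progenitor and mature luminal cells of retired breeders, at 2.28, 3.20 and 4.82 in 9-week virgins and at 8.24, 8.69 and 9.19 at day 10. The 9-week stem and luminal progenitor values lay below the medians of their arrays, and the deposited values do not show how much of such a signal is background. With values below the array median raised to it the difference was 2.73 (adjusted p = 0.0384). In the replicate fit 3 genes passed, and the further 2, named after their values were seen, were the cathepsin Ctsj (4.63, adjusted p = 0.0382) and Gm12888 (4.38, adjusted p = 0.0382). Without that term Ctsj was 4.37 (adjusted p = 0.0936) and Gm12888 6.04 (adjusted p = 0.592). Ctsj lay below the array median on 21 of the 23 arrays and Gm12888 on 15. With such values raised, and no replicate term, the differences were 1.46 (adjusted p = 0.0273) and 3.39 (adjusted p = 0.0011). Csn1s1 was 3.65 ± 0.85 higher (adjusted p = 0.592), Csn2 4.04 ± 1.82 higher (adjusted p = 0.674), Rspo1 2.18 ± 0.55 higher (adjusted p = 0.592) and the 5-methylcytosine oxidase Tet3 -2.49 ± 0.69 (adjusted p = 0.592). An unadjusted p under 0.05 was seen for 1113 genes. Within the arrays other than replicate 1, 2 genes passed; replicate 1 holds no retired breeder array. With only the groups compared 0 passed in limma (765 at an unadjusted p under 0.05).

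Fibroblast and stromal markers shifted up in retired breeders with 0 of 10 past the gene test and 6 higher when adjusted over the list alone (camera adjusted p = 8.76e-06), Pdgfra being 2.26 ± 0.66 higher with an adjusted p of 0.594. Interferon response genes shifted down with 0 of 16 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 8.76e-06). Leukocyte markers shifted up with 0 of 16 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 0.00996). The 3 lists were lost at adjusted p = 0.686 with an estimated correlation. The interferon mean lay between 7.63 and 8.05 in the 3 cell types of retired breeders. The 9-week values are given above. The median change of this list was -0.77, with the replicate term -0.27, and within the arrays other than replicate 1 it was 0.13. There the test, which is relative to all other genes, still gave a downward shift (camera adjusted p = 0.0496, and adjusted p = 0.983 with an estimated correlation). Cell cycle genes shifted up with 0 of 29 past the gene test and 0 when adjusted over the list alone (camera adjusted p = 0.00788, and adjusted p = 0.686 with an estimated correlation), with a median of 0.53. Within the arrays other than replicate 1 their median was 0.93 (camera adjusted p = 1.57e-13, and adjusted p = 0.573 with an estimated correlation). Basal markers did not pass over all arrays (camera adjusted p = 0.12) and had a median of 1.01 within the other arrays (camera adjusted p = 0.0215, and adjusted p = 0.983 with an estimated correlation). Leukocyte markers averaged 7.20 on the retired breeder stem array, the one with the Gapdh excess of 3.77, against 4.56 and 5.15 on the 9-week stem arrays. Quantile normalization moved the median change of all genes in the stem cells from 0.34 to 0.13. Alox12e was lost, with 0 genes past in limma, without the retired breeder stem array (711 at an unadjusted p under 0.05), the retired breeder luminal progenitor array (551), 9-week stem replicate 2 (1776), mature luminal replicate 1 (774) or 2 (1587), or luminal progenitor replicate 1 (636).

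Within stem cells alone, Dmbt1 (-7.71 ± 1.15 log2), Ido1 (-7.22 ± 0.88), Ctse (-6.72 ± 0.90) and Fgb (-6.17 ± 0.71) were lower at day 10 than in 9-week virgins, and Alox12e was 5.96 ± 0.64 higher (adjusted p = 0.0126). Another probe set of Ctse gave 1.70. With low values raised to the array median Alox12e was 3.27 and Ctse -4.38 at day 10, and neither passed. At day 16 the milk protein Wap was 9.61 ± 1.03 higher (adjusted p = 0.00724), Alox12e 5.48 ± 0.78 higher, and Ido1 (-8.62 ± 1.08), Fgb (-8.11 ± 0.87) and Ttc6 (-5.54 ± 0.79) lower. Wap stood at 2.58 in 9-week stem cells, below their array medians, and at 12.19 on the 1 day-16 stem array. Mature luminal cells held 13.14, and which cells of the stem preparation held Wap was not tested. Its difference was 7.21 (adjusted p = 0.00534) with low values raised. Alox12e (2.78), Ido1 (-5.39) and Ttc6 (-3.60) then lost the call. Another Ttc6 probe set gave -1.965 as deposited. Endothelial markers shifted down at day 10 with 0 of 12 past the gene test and 9 lower when adjusted over the list alone (camera adjusted p = 4.42e-15, and adjusted p = 0.0702 with an estimated correlation). Their mean on the stem arrays was 11.50 and 11.11 at 3 weeks, 9.52 and 9.93 at 9 weeks, 6.87 and 6.68 at day 10, 7.28 at day 16 and 8.73 in retired breeders, as the plot of marker lists shows. Of all genes 1 was higher and 8 lower at day 10, with 141 under the replicate term, 167 under the block and 0 with only the groups compared (715 at an unadjusted p under 0.05), and 2 were higher and 7 lower at day 16, with 94 under the replicate term. At 3 weeks 0 passed in limma (831 at an unadjusted p under 0.05, and 32 passing under either the replicate term or the block), and in retired breeders 0 (351 at an unadjusted p under 0.05, and 656 with the replicate term, where 0 passed as well). The day-10 count was 0 without day-10 stem replicate 1 (682 at an unadjusted p under 0.05), 18 without replicate 2, 2 without 9-week stem replicate 1 and 3 without replicate 2. The day-16 count was 0 without 9-week stem replicate 1 (1870 at an unadjusted p under 0.05).

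**Figure D3:**
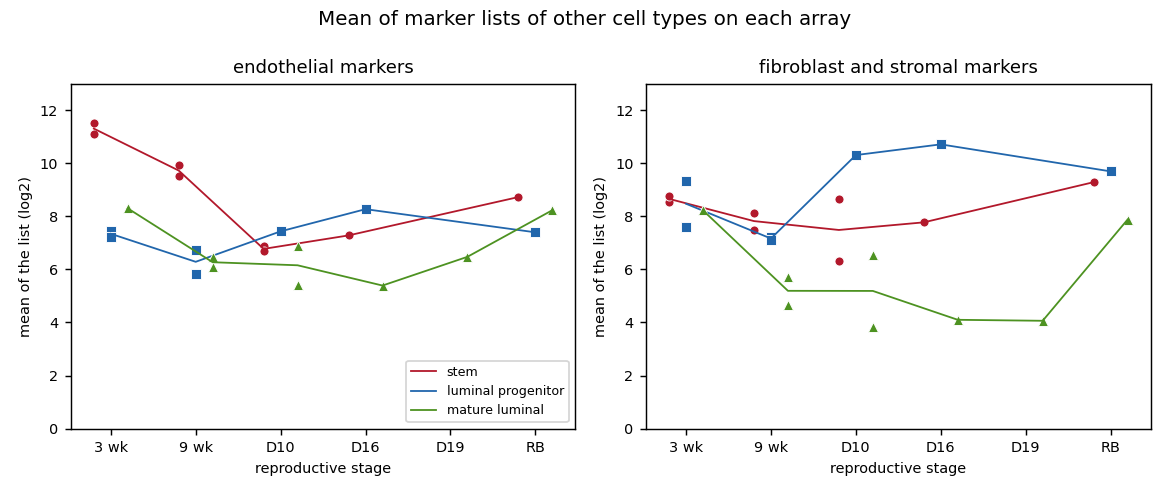
Points are the mean log2 value on each array of 12 endothelial markers (left) and 10 fibroblast and stromal markers (right) by stage (3 wk and 9 wk, virgin; D10, D16 and D19, days of pregnancy; RB, retired breeder), and lines join the means of a cell type. The endothelial mean in stem cells was 9.52 and 9.93 at 9 weeks and 6.87 and 6.68 at day 10, and the fibroblast mean in luminal progenitors stood at 10.31 at day 10 and 10.71 at day 16.

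Within luminal progenitors, Wap (9.07 ± 1.03 log2, adjusted p = 0.00616) and Fabp3 (8.49 ± 1.13) were higher and Fgb (-8.37 ± 0.87) and Krt6a (-7.55 ± 1.19) lower on the day-10 array than in 9-week virgins, with 7 genes higher and 15 lower. The replicate term gave 145 genes, and with only the groups compared 0 passed in limma (1376 at an unadjusted p under 0.05). The count was 3 without 9-week luminal progenitor replicate 1 and 5 without replicate 2. In luminal progenitors 0 genes passed in limma at 3 weeks (201 at an unadjusted p under 0.05), at day 16 (1020, and 9 passing under the replicate term) and in retired breeders (338). Under the replicate term 0 passed at 3 weeks (552) and in retired breeders (529). The values of days 10 and 16 rest on 1 array each. Of 899 genes that moved alike by over 1 log2 unit in the other cell types, 14.7% moved the same way between these arrays.

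Within mature luminal cells the pregnancy change was followed to day 19. At day 10 Csn1s1 (8.21 ± 1.20 log2, adjusted p = 0.0127), the growth factor Igf2 (6.20 ± 0.92, with 2.205 from another probe set) and the fibrillin Fbn2 (6.17 ± 0.79) were higher, and Dmbt1 (-10.51 ± 1.15) and Ido1 (-9.71 ± 0.88) lower. At day 16 Lao1 (10.65 ± 2.36), Thrsp (10.16), Fabp3 (9.45 ± 1.13), Csn1s1 (8.93) and Wap (8.16 ± 1.03, adjusted p = 0.002) were higher, and Pgr (-6.80 ± 1.15, adjusted p = 0.0116, with -1.31 from another probe set), Esr1 (-3.53 ± 0.65, adjusted p = 0.0176) and Krt6a (-10.87 ± 1.19) lower. At day 19 Lao1 (11.06 ± 2.36, adjusted p = 0.0495), the casein Csn1s2b (9.81 ± 1.96), Fabp3 (9.77 ± 1.13), Csn1s1 (8.94 ± 1.48), Wap (8.60 ± 1.03, adjusted p = 0.00274) and Cel (7.24) were higher, and the claudin Cldn10 (-9.23 ± 1.25), Pgr (-7.61 ± 1.15, adjusted p = 0.0105, with -0.78 from another probe set) and Esr1 (-3.29 ± 0.65, adjusted p = 0.0363) lower. Milk protein and secretion genes rose at day 19 for 6 of 15, 14 when adjusted over the list alone (camera adjusted p = 1.18e-22). Fatty acid and triglyceride synthesis rose for 2 of 20, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.46e-11). Hormone-sensing markers fell for 6 of 11, 7 when adjusted over the list alone (camera adjusted p = 1.84e-12). All 3 held at adjusted p = 0.0126 with an estimated correlation.

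In mature luminal cells 24 genes were higher and 45 lower at day 10 (506 under the replicate term, 528 under the block). At day 16 57 were higher and 244 lower (994 under the replicate term), and 54 were higher and 121 lower at day 19 (725 under the replicate term). With only the groups compared the counts were 1, 178 and 98. At 3 weeks 0 passed in limma (1876 at an unadjusted p under 0.05, and 32 passing under the replicate term) and in retired breeders 0 (348 at an unadjusted p under 0.05, and 597 with the replicate term, where 0 passed as well). The day-10 count was 8 without day-10 replicate 1, 15 without day-10 replicate 2, 14 without 9-week replicate 2 and 39 without 9-week replicate 1. The day-16 count was 155 without 9-week replicate 2 and 176 without replicate 1, and the day-19 count 44 without 9-week replicate 2. Only the 1 array of each of these stages and cell types stands behind the values of days 16 and 19.

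Whether stage effects differed between stem and mature luminal cells was tested directly. The day-16 effects differed for 1 gene, the growth factor pleiotrophin, Ptn, with an effect in stem cells above that in mature luminal cells by 5.17 ± 0.48 log2 units (adjusted p = 0.00313). It stood at 13.09 in stem and 13.59 in mature luminal cells of 9-week virgins and at 12.06 and 7.40 at day 16. Of 3 probe sets of Ptn above the filter, 2 gave this direction and the other gave -0.76. With the mean of all probe sets 0 genes passed in limma (647 at an unadjusted p under 0.05), as without the trend (779) and with only the groups compared (419), while the replicate term gave 79 genes and the removal of 9-week stem replicate 2 gave 4. The interactions gave 0 genes in limma at 3 weeks (748 at an unadjusted p under 0.05), at day 10 (869, with 1 gene under the replicate term and 2 under the block) and in retired breeders (199). Under the replicate term 0 passed at 3 weeks (1325) and in retired breeders (548).

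The 3 DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b passed in 0 of their tests over the 8 averaged comparisons in limma, with 0 at an unadjusted p under 0.05. Their log2 differences lay between -0.65 and 0.50, and the smallest adjusted p was 0.282, or 0.0755 with the replicate term. The list of DNA methylation and Polycomb enzymes was 1 of 8 lists with no camera call in these comparisons over all arrays without the replicate term. The others were prolactin and STAT5 pathway, antigen presentation and secretory immunity, cyclin-dependent kinase inhibitors and senescence, and markers of adipocytes, erythroid cells, skeletal muscle and Schwann cells. Over 64 tests of these lists 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0599. With the replicate term the DNA methylation and Polycomb list shifted down from day 10 to day 16 (camera adjusted p = 0.0346, and adjusted p = 0.384 with an estimated correlation), with 0 of 16 members past the gene test and 0 when adjusted over the list alone. Within the arrays other than replicate 1 it did so as well (camera adjusted p = 0.0153). There antigen presentation shifted up at day 10 (0.0415), the prolactin and STAT5 pathway in mature luminal cells against luminal progenitors (0.0492) and skeletal muscle markers from day 10 to day 16 (0.0481). With an estimated correlation these 4 were lost, at an adjusted p of 0.621, 0.658, 0.468 and 0.621.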

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

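The tests of an exchange of arrays, of the share of luminal cells and of the replicate numbers were chosen after the results were seen, while the tests with second marker lists and with other splits were set beforehand.

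A difference between groups in the effect of day-16 pregnancy stood out for Ptn, whose effect in stem cells lay 5.165 ± 0.48 log2 units above that in mature luminal cells (limma adjusted p = 0.00313). Mature luminal cells held 7.40 on the 1 array of day 16 and 7.65 on that of day 19, against 13.59 at 9 weeks. Day 16 has 1 array per cell type, and no explanation was tested for this gene.

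The day-10 and day-16 luminal progenitor arrays stood against the other cell types, since 14.7% of 899 genes that moved by over 1 log2 unit alike in stem and mature luminal cells between these days moved the same way in luminal progenitors, with a median of -1.18 in the direction of the others. With the arrays of another cell type in that place, the share was 51.4% of 181 genes for stem cells and 38.4% of 315 genes for mature luminal cells. Those genes were chosen partly by the luminal progenitor arrays in question, so these shares are no independent reference. A lower share of luminal cells on the day-16 array stays open. Luminal keratin and junction genes differed by a median of 0.045 (quartiles -0.04 and 0.20) and milk protein genes by -1.52. This is weak, as luminal progenitors exceed stem cells in the first list by only 0.77 (replicate 1) and 0.91 (other arrays). On that array 19 of 19 basal (median 0.68) and 11 of 12 endothelial markers were higher, and leukocyte markers had -0.42. An exchange of the pair of arrays may account for the pattern; a difference in how luminal progenitors pass through pregnancy stays open as well, with 1 array a day, and the labels were used as given.

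Endothelial genes were lower in the stem preparations of day 10 than in those of 9-week virgins. A second list of 20 endothelial genes that shares none with the first had a median change of -2.60, with 20 of 20 lower, which is consistent with fewer endothelial cells in the day-10 preparation. The replicate numbers do not account for it, since the first list had medians of -2.46 within replicate 1 and -2.67 within replicate 2. Levels at 9 weeks were high, with Plvap at 10.53, Kdr at 10.36 and Emcn at 9.95, against 8.14, 4.50 and 5.67 at day 10. Lower expression within endothelial cells or within the stem cells themselves stays open, and the labels used here name no gate that would remove endothelial cells.

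Fibroblast genes were higher in luminal progenitors than in mature luminal cells. A second list of 20 fibroblast genes that shares none with the first had a median difference of -2.21, with 20 of 20 lower in mature luminal cells, which is consistent with more fibroblasts in the luminal progenitor preparations. The replicate numbers do not account for it, since the first list had medians of -1.21 within replicate 1 and -3.43 on the other arrays. On the day-16 arrays Col3a1 stood at 12.89 in luminal progenitors and 5.76 in mature luminal cells, and Col1a1 at 11.61 and 4.37. Expression of these genes by luminal progenitors stays open, and the labels used here name no gate that would remove fibroblasts.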

How the results depend on the processing

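The replicate term on all arrays, the fits and list tests within either side of the replicate split, the fit without the luminal progenitor arrays of days 10 and 16, the raised low values and the lists without the 3-week mature luminal array were chosen after the data were seen, and the other settings were planned. Of 33 results given as counts, 178 of 240 settings that left out 1 array and 220 of 311 other settings stayed within 1.5 times. Of the named genes, 2203 values under the other settings kept their direction and their side of the threshold, 354 kept the direction and lost the call, and 41 gained one; with 1 array left out these were 1736, 370 and 14, and 0 reversed. The 1 reversal was S100a8 in luminal progenitors against stem cells, at -0.18 within the arrays titled replicate 1. Fits on fewer arrays have fewer degrees of freedom, or average over fewer stages or cell types where the only array of a group was left out. For the other changes the cause was not tested. The alternative log2(value + 16) was not run, because the deposited values were already on the log2 scale. Signal over background was not used here as a limit, since a value at 0 is a floor.

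The replicate numbers pair the arrays. The replicate block on the numbered groups of 2, which averages only over stages or cell types with 2 arrays, gave 1744 genes for luminal progenitors against stem cells, 2 for mature luminal cells against luminal progenitors, 17 for 3-week virgins and 798 for day 10. Within stem cells it gave 32 at 3 weeks and 167 at day 10, within mature luminal cells 528 at day 10, and 2 for the day-10 interaction. It moved no other count by more than 1.5 times. Of 132 values of named genes under the block, 107 kept their side of the threshold, 21 lost the call and 4 gained one, all in the same direction.

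With the replicate term on all arrays the counts were 2220 for luminal progenitors against stem cells, 3023 for mature luminal against stem cells, 153 for mature luminal cells against luminal progenitors, 408 for 3-week virgins, 1282 for day 10, 1118 for day 16 and 3 for retired breeders. Within stem cells they were 32 at 3 weeks, 141 at day 10 and 94 at day 16. Within luminal progenitors they were 145 at day 10 and 9 at day 16, and within mature luminal cells 32, 506, 994 and 725 at 3 weeks and days 10, 16 and 19. The interactions gave 1 at day 10 and 79 at day 16. In the list tests 9 lists shifted between days 10 and 16.

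Within the arrays titled replicate 1 the counts were 366 for luminal progenitors against stem cells, 322 for mature luminal against stem cells, 1 for mature luminal cells against luminal progenitors and 0 for 3-week virgins in limma (640 at an unadjusted p under 0.05). Within the other arrays they were 9 for 3-week virgins, 80 for day 10, 199 for day 16 and 2 for retired breeders.

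Without the luminal progenitor arrays of days 10 and 16 the counts were 1 for mature luminal cells against luminal progenitors, 157 for day 10 and 15 for day 16 against day 10. With only the groups of a comparison they were 1 for mature luminal cells against luminal progenitors, 1 for 3-week virgins, 176 for day 10, 135 for day 16 and 0 in limma for retired breeders (765 at an unadjusted p under 0.05). They were 0 for day 10 within stem cells (715) and within luminal progenitors (1376), 1, 178 and 98 for days 10, 16 and 19 within mature luminal cells, and 0 for the day-16 interaction (419).

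Without the filter 1 gene passed for 3-week virgins and 3 for retired breeders. The filter at the 60th percentile gave 2 for day 16 within luminal progenitors and 6 for the day-16 interaction. The mean of all probe sets gave 42 for 3-week virgins, 5 and 4 for days 10 and 16 within stem cells, 1 for the day-10 interaction and 0 in limma for that of day 16 (647). Quantile normalization gave 37 for mature luminal cells against luminal progenitors and 1 for 3-week virgins. Without the trend the counts were 2 for 3-week virgins, 331 for day 16, 4 and 199 for day 16 within stem and mature luminal cells, and 0 in limma for the day-16 interaction (779). Robust moderation gave 1 for 3-week virgins, and the additive model 1065 for luminal progenitors against stem cells, 2 for 3-week virgins and 3 for retired breeders.

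With values below the array median raised to it the counts were 45 for mature luminal cells against luminal progenitors, 301 for 3-week virgins and 6 for retired breeders. Within stem cells they were 75, 22 and 47 at 3 weeks and days 10 and 16, and within luminal progenitors 127, 13 and 4 at days 10 and 16 and in retired breeders. Within mature luminal cells they were 269, 114 and 5 at 3 weeks, day 10 and in retired breeders, and for the interactions 40 at 3 weeks and 9 at day 16. Of 274 genes gained for 3-week virgins 26 lay at or below the median on every array of the groups of 2, and of 269 gained in mature luminal cells 54 did. Of 202 values of named genes 187 kept their side of the threshold, 9 lost the call and 6 gained one.

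Camera with an estimated correlation left 0 lists for luminal progenitors and for mature luminal cells against stem cells, for 3-week virgins, for day 16 against day 10 and for retired breeders (5, 7, 1, 3 and 0 at an unadjusted p under 0.05). It left 2 for mature luminal cells against luminal progenitors, 1 for day 10 and 1 for day 16.

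With 1 array left out at a time the counts ran from 311 to 929 for luminal progenitors against stem cells, 683 to 1696 for mature luminal against stem cells, 0 to 63 for mature luminal cells against luminal progenitors, 0 to 4 for 3-week virgins, 152 to 385 for day 10, 28 to 596 for day 16, 0 to 15 for day 16 against day 10 and 0 to 1 for retired breeders. Within stem cells they ran from 0 to 18 at day 10 and 0 to 5 at day 16, and within luminal progenitors from 3 to 5 at day 10. Within mature luminal cells they ran from 8 to 39, 155 to 176 and 44 to 132 at days 10, 16 and 19, and for the day-16 interaction from 1 to 4. The numbers of lists that shifted ran from 6 to 15 for mature luminal cells against luminal progenitors (15 without the 3-week mature luminal array), 7 to 13 for day 10 (7 without the day-10 luminal progenitor array), 3 to 9 for day 16 against day 10 and 5 to 10 for retired breeders (5 without 9-week stem replicate 1). For day 16 against day 10 it was 3 without the day-16 stem array and 9 without either luminal progenitor array or day-10 mature luminal replicate 1.

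Quantile normalization moved the median of all genes by over 0.1 in comparisons within a cell type as well. The shift was -0.12 for 3-week and -0.21 for retired breeder stem cells, and -0.32, 0.11 and 0.11 for mature luminal cells at 3 weeks and days 16 and 19. For the interactions it was 0.17 at 3 weeks, -0.16 at day 16 and -0.19 in retired breeders.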

Other observations

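The counts over other splits of the arrays were planned, and the values within replicates, the splits with an equal replicate balance and the values of haemoglobin and of the list interactions were picked after they were seen.

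Within mature luminal cells of day 10, cell cycle genes were the list with the smallest p. Of 29 genes 0 passed in limma over all genes, and 18 were higher when adjusted over the list alone (camera adjusted p = 1.15e-17, and adjusted p = 0.128 with an estimated correlation). The stage effect on this list at day 10 was lower in stem than in mature luminal cells, with a median difference of -1.17 (camera adjusted p = 6.03e-06, and adjusted p = 0.509 with an estimated correlation). It was -1.90 within replicate 1 and -0.27 within replicate 2. The day-10 effect on endothelial markers was also lower in stem than in mature luminal cells, with a median difference of -2.86 and 7 of 12 lower when adjusted over the list alone (camera adjusted p = 5.46e-11, and adjusted p = 0.224 with an estimated correlation), and it was -1.59 and -4.10 within replicates 1 and 2. At day 16 the effect on hormone-sensing markers was higher in stem than in mature luminal cells, with a median difference of 3.20 and 4 of 11 higher when adjusted over the list alone (camera adjusted p = 8.74e-07, and adjusted p = 0.129 with an estimated correlation). It was 2.47 against the 9-week arrays of replicate 1 and 4.45 against those of replicate 2.

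The haemoglobin chain Hbb-b2, which marks red cells, varied beyond the 3-week arrays. It stood at 3.96 to 5.12 in the cell types of 9-week virgins, at 11.73 on the day-10 luminal progenitor array, at 10.62 on the day-16 stem array and at 9.87 on the day-19 mature luminal array, and its 2 day-10 stem arrays held 1.16 and 7.39.

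Splits of the same arrays within stage or cell type were counted, the real one included. Other splits put arrays of different stages or cell types into the same group, which widens the estimated spread and lowers their counts. A low share therefore argues only against no difference at all, and cannot exclude an accident of grouping for the genes counted. As many genes came from 1 of 100 splits for luminal progenitors against stem cells (673 genes, with 0 in the highest other split), from 1 of 100 for mature luminal against stem cells (1283 against 166) and from 1 of 100 for day 10 (330 against 128), each a share under 0.05. For mature luminal cells against luminal progenitors 3 of 100 gave as many (19 against 25), and for 3-week virgins 4 of 100 (27 against 2920). These shares lie under 0.05 too, without adjustment over the comparisons. The split with 2920 genes followed the replicate number, and points to that structure of the arrays; within the sides of the replicate split the real comparison had 0 and 9 genes. Among the splits drawn with the replicate balance of the real one, the real one alone gave as many in these 5 comparisons, at 4%, 2.7%, 3.13%, 2.56% and 3.23% of 25, 37, 32, 39 and 31 splits in the order given. For day 16 it was 1 of 27 (505 against 129), where the split with 129 genes followed the replicate number. Only 8 splits have the balance of the real one, too few for a share under 0.05, and the highest other of these had 37. For retired breeders 2 of 27 splits gave as many genes (1 against 1574), so an accident of grouping was not excluded. The split with 1574 genes followed the replicate number too, and the real comparison had 3 genes with the replicate term. For day 16 against day 10 there were 18 splits, too few for a share under 0.05; the real count was 0 in limma (212 at an unadjusted p under 0.05), all 18 gave as many, and the highest other had 24.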
